A study of Homo sapiens with 60 samples.

How the data were processed

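HT29 cells, an established line derived from a human colorectal adenocarcinoma, were treated for 24 h with water extracts of medicinal plants or of herbal formulae at 500, 100 or 20 µg/mL, or with the vehicle dimethyl sulfoxide. The sample labels give the vehicle as 0.1% dimethyl sulfoxide, while the design text of the series gives 2%, and which of these was used was not settled here. The design text also states that an extract whose 20% inhibitory concentration lay below the top dose was used at that concentration and its dilutions. The sample labels used here give the 3 nominal doses for every extract. Per the labels' protocols, RNA with an integrity number above 7 was made into strand-marking libraries and sequenced as paired reads of 100 bases. Other treatments named in the design text, among them ethanol extracts and inhibitors used as positive controls, were not analysed here.

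The deposited table holds RSEM expected counts per gene, that is, estimated counts that need not be whole, for 60675 Ensembl genes, without further normalization. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a, RSEM 1.3.3 and the GRCh38 (hg38) genome were used. The notes as used here give no role or order for these names, and the annotation release and the strand setting are not given in the sources used here. Of the values, 8.8% were not whole, and all were rounded to whole numbers before use. Expected counts divide reads that match several genes among them, so values of near-identical genes, such as the AKR1C genes, the metallothioneins and HSPA1A with HSPA1B, are uncertain relative to each other. The same holds for overlapping and readthrough genes and, since the strand setting is not known, for antisense genes. The table has 273 columns of values, of which the 60 that the labels tie to these samples were used, and the other 213 were not. Gene symbols came from a table of gene names for 56558 identifiers and from GENCODE release 29 for 497, and 3620 had no symbol. Coordinates are those of GENCODE release 29 on GRCh38.

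The 60 libraries held 20459346 to 36253747 counts each. Groups were taken from the sample labels. The vehicle and the 18 treated groups of Cnidii Rhizoma, Rehmanniae Radix Preparata, Cinnamomi Cortex, Astragali Radix, Sagunja-tang and Samul-tang had 3 libraries each, 57 in all. Paeoniae Radix had 1 library per dose and entered none of the tested comparisons. For its top dose, gene lists were only ranked among random lists of like size and expression. Replicates correlated at 0.9939 to 0.998 (Pearson, log2 CPM), and the 57 replicate pairs differed by 2.52 to 29.16 times the chi-square expected from counting alone, so that no pair was treated as one library deposited more than once. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

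The main test was edgeR 4.0.16's quasi-likelihood test (R 4.3.3) with TMM factors, which ran from 0.938 to 1.043, on all 57 libraries with 1 coefficient per group and no block. Genes were kept by filterByExpr with a minimum count of 10, which left 16356. The common biological coefficient of variation was 0.057. P-values were adjusted by the Benjamini-Hochberg method within each of 27 comparisons, and a gene was called at an adjusted p under 0.05. Where counts at an unadjusted p under 0.05 are given, a share of 0.05 of the 16356 genes would reach it without any change. Each treated group was compared with the vehicle, 500 with 20 µg/mL within each extract, and Samul-tang at 500 µg/mL with Cnidii Rhizoma, Rehmanniae Radix Preparata and Sagunja-tang at the same dose. Fold changes are on the log2 scale with standard errors (SE), and levels are CPM, counts scaled to library size, as mean ± SD.

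Gene lists, 33 in number and including markers of fibroblasts, leukocytes and hepatocytes, were tested with camera in limma 3.58.1, which compares a list with all other genes, at a preset correlation of 0.01, with adjustment over the 33 lists. The same test was run with the correlation estimated for each list. The test, the libraries, the lists, the alternatives and the rule for named genes were fixed before the data were examined. At 500 µg/mL against the vehicle, that rule took the 6 higher and 6 lower called genes with the largest fold change that had a mean log2 CPM of at least 1, all 3 treated libraries on the same side of all vehicle libraries and an ordinary symbol. It added up to 4 members of each list past its test and up to 2 called members of other lists, and 5 higher and 5 lower genes for the remaining tested comparisons. A panel of 15 genes could be named whatever its values. For Paeoniae Radix the rule took the panel and the 5 higher and 5 lower genes at 500 µg/mL that kept their direction against every vehicle library at all 3 doses. Genes named outside the rule are said to be so, and some genes that the rule takes are not reported here.

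Counts of 16356 genes were simulated for all 57 libraries from the means over all libraries and the fitted dispersions. Changes were put only into Cnidii Rhizoma at 500 µg/mL, which was tested against the vehicle. At each size 50 genes were changed, drawn from those with a mean count of at least 50. The test recovered 70% of genes changed 1.25-fold, 86% at 1.5-fold, 100% at 2-fold and 100% at 3-fold. A list of 25 other genes was shifted by 0.2 on the log2 scale, and 6 of them were called. In all the test made 188 calls, of which 4 were false, and 0 calls in a simulated comparison without change. The simulation held no difference between sets of libraries, and recovery among genes with lower counts was not tested.

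Alternatives fixed beforehand were RLE factors, DESeq2 1.42.0, no filter on low counts, a fit of the 2 groups alone, the replicate number as a block, each library left out in turn, and an estimated correlation for the lists. Chosen after the data were seen were a library set term, a fit of the first library set alone, and an adjusted p under 0.1 for the comparisons between extracts. The library sets were read from the sample codes, with the boundary placed after the first principal component had been seen. The first set holds the vehicle, the libraries of code 5 (Cnidii Rhizoma and Rehmanniae Radix Preparata) and replicate 1 of code 6 (Cinnamomi Cortex and Astragali Radix). The second holds replicates 2 and 3 of code 6 and all libraries of code 7 (both formulae). The sample titles name the same batch, BatchB, for all 60 libraries, and no label states that these sets are batches. Figures were drawn with matplotlib 3.10.9.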

Results

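RNA-seq counts were analysed for 60 libraries of HT29 colorectal adenocarcinoma cells treated for 24 h with water extracts of tonifying herbal medicines or with the vehicle. The vehicle had 3 libraries, with totals of 26614906, 24034584 and 20701950 counts. Cnidii Rhizoma, Rehmanniae Radix Preparata, Cinnamomi Cortex and Astragali Radix are single plant drugs, and Sagunja-tang and Samul-tang are formulae made from several. Each had 3 libraries at 500, 100 and 20 µg/mL. Paeoniae Radix had 1 library per dose. Total counts over all libraries ran from 20459346 to 36253747.

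The libraries did not separate by treatment alone. The first principal component held 15.7% of the variance and parted the vehicle, Cnidii Rhizoma, Rehmanniae Radix Preparata and replicate 1 of Cinnamomi Cortex and Astragali Radix from both formulae and the other replicates of those plants, with 1 exception, replicate 2 of Cinnamomi Cortex at 500 µg/mL, which lay at -16.02 among the former. These sides are called the first and second library set, with 27 and 30 libraries, and the exception was left in the second set that its sample code gives. The dependence of log2 CPM on GC content also differed, with a slope per 10 percentage points of -0.027 ± 0.014 (SD) in the first set and 0.025 ± 0.031 in the second. All vehicle libraries are in the first set and all formula libraries in the second. For the formulae a comparison with the vehicle is therefore also one between sets, and counts are given without and with a library set term, which was added after the data were seen and rests on the 6 groups of Cinnamomi Cortex and Astragali Radix that lie in both sets. Comparisons of 500 with 20 µg/mL within an extract, and of the formulae with each other, are balanced over the sets by sample code, but for Cinnamomi Cortex not by the first principal component, because of that exception.

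**Figure D1:**
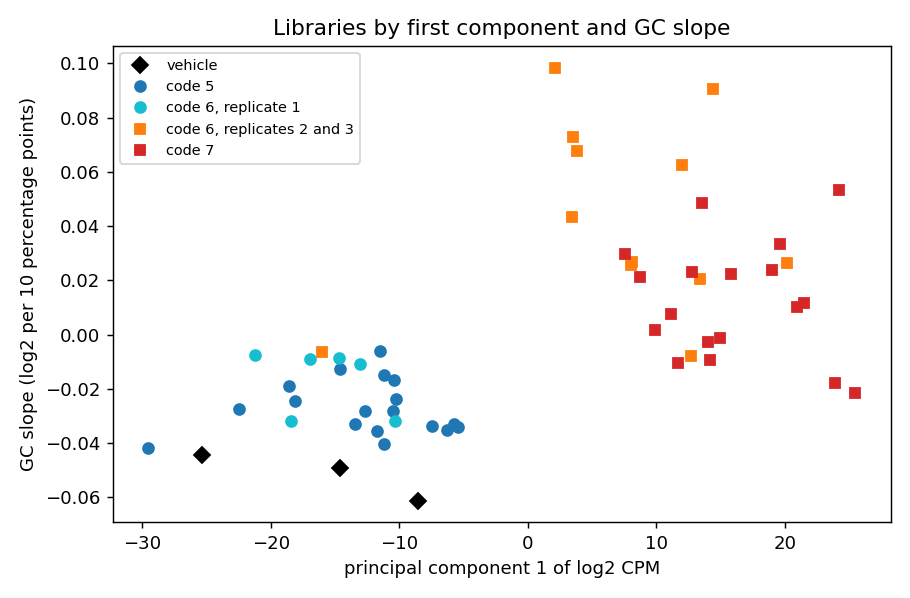
Each point is 1 of the 57 libraries of groups with 3 replicates, placed by its first principal component of log2 CPM (x axis) and by the slope of its log2 CPM on GC content per 10 percentage points (y axis), with colours for the sample codes. The vehicle, code 5 and replicate 1 of code 6 lie at or below -5.4 on the first component, and all other libraries lie above 0 except 1 of code 6 at -16.02.

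Several genes described here lie at these places in GRCh38 (GENCODE release 29), and all are annotated as protein-coding. AKR1C2 (ENSG00000151632) lies on chromosome 10 from 4987400 to 5018031 and AKR1B10 (ENSG00000198074) on chromosome 7 from 134527592 to 134541408. The chemokine genes CXCL8 (ENSG00000169429), from 73740506 to 73743716, and CXCL1 (ENSG00000163739), from 73869393 to 73871242, both lie on chromosome 4, and CCL20 (ENSG00000115009) lies on chromosome 2 from 227805739 to 227817564. PI3 (ENSG00000124102) lies on chromosome 20 from 45174876 to 45176544, as does ACSS2 (ENSG00000131069) from 34872146 to 34927962. MT2A (ENSG00000125148), from 56608199 to 56609497, and MT1X (ENSG00000187193), from 56682424 to 56684196, lie on chromosome 16, and HMOX1 (ENSG00000100292) lies on chromosome 22 from 35380361 to 35394214.

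The first question was what each extract changed relative to the vehicle. Cinnamomi Cortex, the bark of the cinnamon tree, raised genes of several groups at 500 µg/mL. Of 25 tested targets of NRF2, the transcription factor of the antioxidant response, 23 rose and 0 fell (24 and 0 adjusted over the list alone; camera adjusted p = 3.2e-41). AKR1C2, an aldo-keto reductase, rose by 1.69 (log2, SE 0.09, adjusted p = 1.8e-19), from 11 ± 1.17 CPM in the vehicle to 35.6 ± 1.89 (n = 3 each), AKR1C1 by 1.45 and AKR1B10 by 1.01. Of 25 genes of cholesterol synthesis 23 rose and 0 fell (24 and 0 adjusted over the list alone), among them LSS by 0.80, TM7SF2 by 0.68 and DHCR7 by 0.58. Of 14 genes of fatty acid synthesis 8 rose and 0 fell (10 and 0 adjusted over the list alone), with ACSS2 at 1.14 (SE 0.08) and SCD at 0.55. These calls held with an estimated correlation, with adjusted p = 1.2e-07 for the NRF2 list, 0.00064 for cholesterol synthesis and 2.2e-06 for fatty acid synthesis.

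Of 31 genes of the ATF4 amino acid response 20 rose and 1 fell with Cinnamomi Cortex at 500 µg/mL (22 and 1 adjusted over the list alone), including CHAC1 at 0.90 (SE 0.16), TRIB3 at 0.88 (SE 0.09) and ASNS, asparagine synthetase, at 0.40, while DDIT3 was at 0.00 (SE 0.12, adjusted p = 1). Of 13 genes of iron uptake and storage 4 rose (5 adjusted over the list alone), among them HMOX1, heme oxygenase, at 0.88 and both ferritin subunit genes, FTL at 0.51 and FTH1 at 0.39. Of 9 metallothionein and zinc response genes 5 fell and 1 rose (5 and 1 adjusted over the list alone). MT1X fell by 2.14 on the log2 scale, MT2A by 1.65 and MT1E by 1.60, while SLC39A10, a zinc importer, rose by 0.94 (SE 0.05). With an estimated correlation these lists stood at adjusted p = 0.00011, 0.00072 and 0.0065. The cell cycle inhibitor CDKN1A was higher by 0.76 (SE 0.08) and KRT20, a keratin of differentiated intestinal cells, by 0.46. CENPE, a kinesin of mitosis, was at -1.30 (SE 0.12) and ANKDD1A at -2.42 (SE 0.23). Of 38 interferon response genes 9 fell and 0 rose (10 and 0 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.17).

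In total 2078 genes were called with Cinnamomi Cortex at 500 µg/mL, 996 higher and 1082 lower, 1282 at 100 µg/mL and 277 at 20 µg/mL. With the library set term the counts were 1910, 237 and 36, of which 1327, 224 and 35 were also called without it. At 100 µg/mL the NRF2 list had 8 risen members (10 risen and 1 fallen adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.15), and at 20 µg/mL 0 (adjusted p = 0.96). MT2A stood at 13.6 ± 1.54, 26.7 ± 7.31 and 33.9 ± 5.08 CPM at 500, 100 and 20 µg/mL, against 42.9 ± 3.73 in the vehicle. Without replicate 3 the count at 500 µg/mL was 1111. Without Cinnamomi Cortex replicate 1 the counts at 100 and 20 µg/mL were 2503 and 1223, and without replicate 2 they were 139 and 42.

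**Figure D2:**
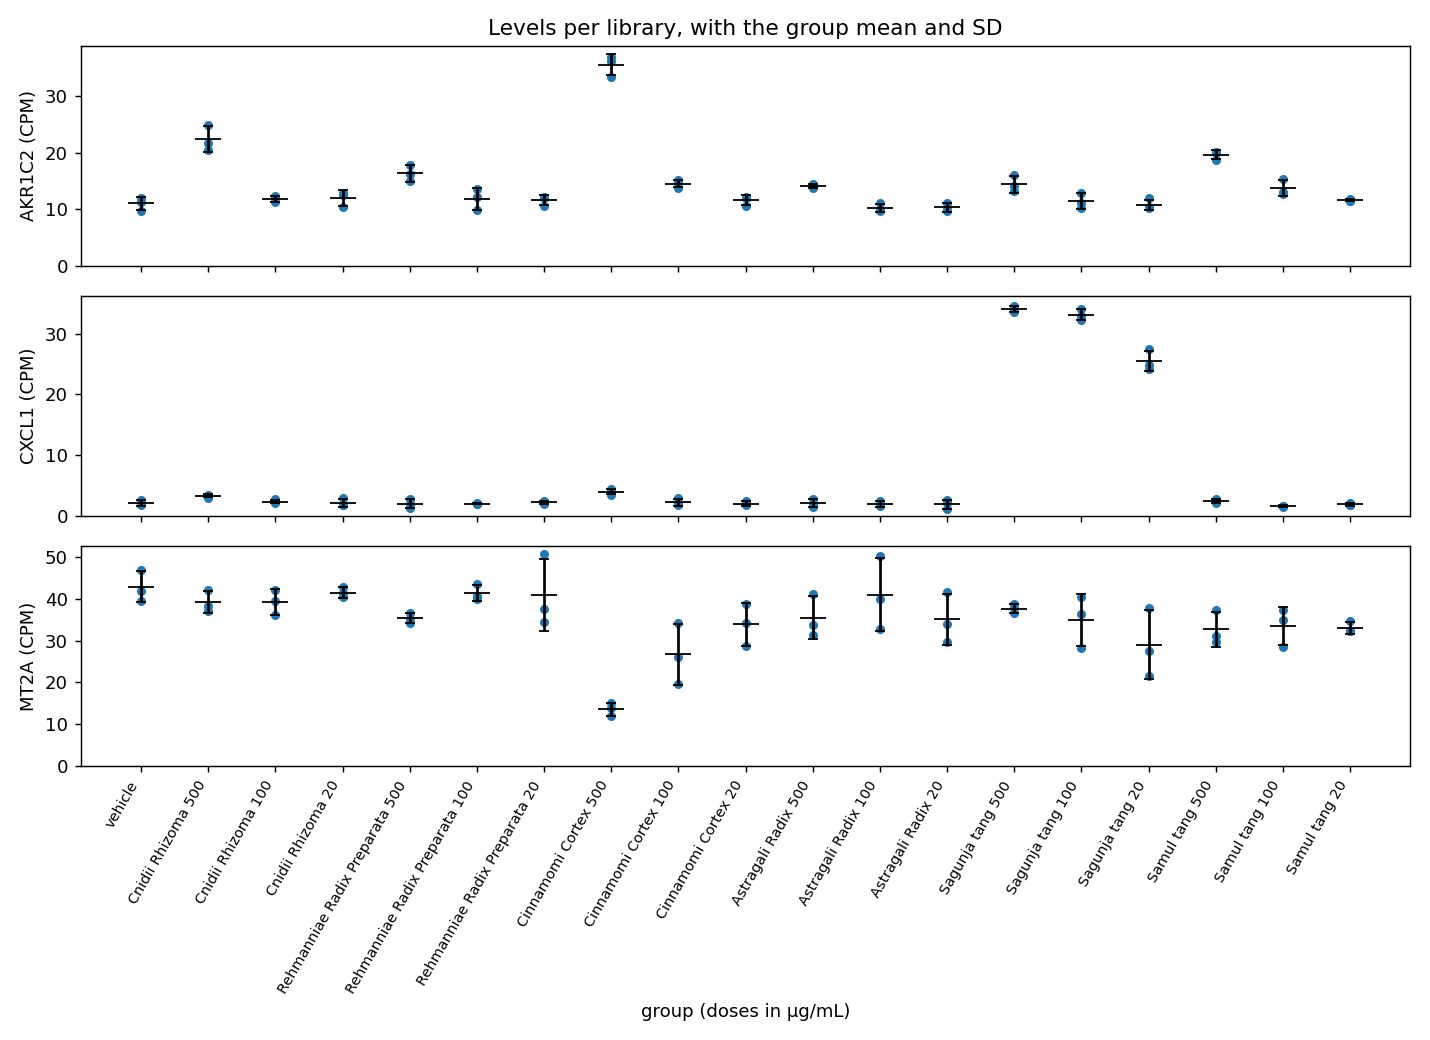
Levels of AKR1C2, CXCL1 and MT2A in CPM (y axes) are shown for each library (points) with the group mean and SD (black), for the vehicle and 18 treated groups (x axis, doses in µg/mL). The AKR1C2 mean reaches 35.6 CPM with Cinnamomi Cortex at 500 µg/mL, the CXCL1 means lie at 25.5 to 34 CPM with Sagunja-tang and the MT2A mean at 13.6 CPM with Cinnamomi Cortex at 500 µg/mL.

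Cnidii Rhizoma raised a narrower set at 500 µg/mL. Of the 25 NRF2 targets 18 rose and 0 fell (23 and 0 adjusted over the list alone; adjusted p = 1.8e-08 with an estimated correlation), led by AKR1C2 at 1.03 (SE 0.10, adjusted p = 1.2e-10) and AKR1B10 at 0.98 (SE 0.06), with AKR1C3 at 0.74 and NQO1, a quinone reductase, at 0.38. ALDH3A1 and UGT1A6, enzymes of detoxification, were higher by 0.64 and 0.51. Of 42 genes of S phase and DNA replication 6 rose (24 adjusted over the list alone), each by a small amount, for example MCM3 by 0.20 and RRM2 by 0.16. Of 28 FOXO targets 3 fell (8 adjusted over the list alone), including KLHL24 at -0.41, and of 20 WNT targets 4 fell (6 adjusted over the list alone), including DKK1 at -0.44, AXIN2 at -0.25 and SOX9 at -0.24. Of 24 goblet and secretory genes 2 fell (6 adjusted over the list alone), the mucin genes MUC12 and MUC13 at -0.53 and -0.36, the former with an adjusted p of 0.051 with RLE factors. With an estimated correlation these 4 lists stood at adjusted p = 5.7e-06, 0.00051, 0.014 and 0.0073. Genes called numbered 225 at 500 µg/mL (113 higher, 112 lower), 24 at 100 µg/mL and 48 at 20 µg/mL. All Cnidii Rhizoma libraries are in the vehicle's set, and a fit of that set alone gave 268, 31 and 56. The lower GC slope of the vehicle libraries remains in that fit. Without Cnidii Rhizoma replicate 3 the count at 500 µg/mL was 81, and without replicate 2 that at 20 µg/mL was 4. Without vehicle replicate 1 the edgeR count at 100 µg/mL was 0, against 1078 genes at an unadjusted p under 0.05 and 44 by DESeq2 with all libraries.

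Rehmanniae Radix Preparata, the processed root of Rehmannia, showed the NRF2 list at a smaller size. At 500 µg/mL 9 of 25 members rose and 0 fell (19 and 0 adjusted over the list alone; adjusted p = 1.2e-06 with an estimated correlation), with AKR1C2 at 0.57 (SE 0.10), AKR1B10 at 0.42 and ME1, malic enzyme, at 0.33. HMOX1 was higher by 0.47 (SE 0.08, adjusted p = 0.0012). Of the 20 WNT targets 2 fell (3 adjusted over the list alone), AXIN2 at -0.30 and SOX9 at -0.22. SELENOW, a selenoprotein gene, was at -0.42 (SE 0.05) and RIGI, a sensor of viral RNA, at -0.38. The calls numbered 97 at 500 µg/mL (58 higher, 39 lower), 33 at 100 µg/mL and 72 at 20 µg/mL, where 69 were higher. With vehicle replicate 2 left out the count at 500 µg/mL was 27, and with Rehmanniae Radix Preparata replicate 3 left out those at 100 and 20 µg/mL were 6 and 14.

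Astragali Radix changed few named genes by much. Of 42 genes of S phase and DNA replication 15 rose and 0 fell at 500 µg/mL (30 and 0 adjusted over the list alone; adjusted p = 0.00011 with an estimated correlation), among them E2F1, a transcription factor of cell cycle entry, at 0.49 (SE 0.09), MCM3 at 0.25 and MCM5 at 0.22. E2F1, MCM3 and MCM5 stood at 65.1, 203 and 116 CPM, against 46.2, 170 and 99.5 in the vehicle. With Samul-tang at 20 µg/mL they stood at 60.8, 192 and 108 CPM. Levels above the vehicle were therefore not particular to Astragali Radix. Of 20 WNT targets 4 fell and 2 rose (6 and 2 adjusted over the list alone), with SOX9 at -0.31 and AXIN2 at -0.27. These 2 genes kept their calls with the library set term. DKK1 at -0.41 and EPHB3 at 0.40 lost theirs (adjusted p = 0.061 and 0.41). In all, 4 lists were called with Astragali Radix at 500 µg/mL, and 2 with an estimated correlation. Genes taken by size of change included MAMDC4 at 1.17, CCDC78 at 0.95, PGGHG at 0.91 and TMEM238 at 1.90 (SE 0.42), the last with an adjusted p of 0.092 with the library set term. The first 3 of these are not particular to Astragali Radix, since each was called higher in 17 of the 18 comparisons with the vehicle. Genes called numbered 591, 397 and 228 at 500, 100 and 20 µg/mL, and with the library set term 124, 82 and 37, with 6 members of the S phase list risen at 500 µg/mL. Without replicate 1 of Astragali Radix, the replicate in the vehicle's set, the counts were 1201, 1247 and 1656, and without replicate 3 they were 110, 68 and 26.

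Sagunja-tang raised inflammatory genes at every dose. Of 24 NF-kB inflammatory genes 18 rose and 0 fell at 500 µg/mL (19 and 0 adjusted over the list alone; adjusted p = 9.7e-11 with an estimated correlation), 19 rose at 100 µg/mL (21 adjusted over the list alone) and 17 at 20 µg/mL (19 adjusted over the list alone). CXCL1, a chemokine that attracts neutrophils, rose by 4.02 (log2, SE 0.17, adjusted p = 1.7e-23) at 500 µg/mL, and CXCL8, another of this kind, by 2.46 (SE 0.10). CCL20 rose by 5.08 (SE 0.27), from 0.198 ± 0.0527 to 6.92 ± 0.425 CPM, and CXCL6 by 3.82. PI3, which encodes the protease inhibitor elafin, rose by 2.29 and CEACAM7 by 2.24. CXCL1 stood at 34 ± 0.477, 33.1 ± 0.931 and 25.5 ± 1.69 CPM at 500, 100 and 20 µg/mL, against 2.12 ± 0.478 in the vehicle, and CXCL8 at 31.2 ± 3.03, 31 ± 1.55 and 26.7 ± 1.06, against 5.70 ± 0.313 (n = 3 each). With the library set term CXCL1 was at 4.48 and CXCL8 at 2.47. Of 38 interferon response genes 12, 15 and 20 rose at 500, 100 and 20 µg/mL, with CMPK2 at 1.04 and IFI27 at 0.83 at 500 µg/mL (17, 19 and 21 rose adjusted over the list alone), and with an estimated correlation the adjusted p was 0.15, 0.067 and 0.037.

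The number of genes called with Sagunja-tang was 3252 at 500 µg/mL (1898 higher, 1354 lower), 2664 at 100 µg/mL and 2955 at 20 µg/mL, and with the library set term 341, 100 and 99, of which 285, 90 and 93 were called both ways. Of 13 mitochondrially encoded mRNAs 11 fell at 500 µg/mL without that term (12 adjusted over the list alone; adjusted p = 0.3 with an estimated correlation) and 0 with it, and their share of all counts was 6.642% ± 0.383 against 10.004% ± 1.355 in the vehicle. Without vehicle replicate 3 the counts at 500 and 100 µg/mL were 1306 and 784, and without Sagunja-tang replicate 3 that at 20 µg/mL was 1150.

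Samul-tang, whose ingredients include Cnidii Rhizoma, Rehmanniae Radix Preparata and Paeoniae Radix, raised 19 of 25 NRF2 targets at 500 µg/mL, with 0 fallen (21 and 0 adjusted over the list alone; adjusted p = 0.00065 with an estimated correlation). AKR1C2 was higher by 0.84 (SE 0.10, adjusted p = 8.4e-08), AKR1B10 by 0.62 (SE 0.06), NQO1 by 0.43 and ME1 by 0.40, and with the library set term these were 0.82, 0.61, 0.36 and 0.41, with 12 members of the list risen. Of 20 WNT targets 8 fell and 1 rose (9 and 1 adjusted over the list alone), including SOX9 at -0.35 and AXIN2 at -0.30, and 3 fell with the library set term. SOX9 stood at 151 ± 2.95 CPM at 500 µg/mL and 149 ± 3.94 at 20 µg/mL, against 192 ± 15.8 in the vehicle. AXIN2 stood at 75.1 ± 3.96 and 73.1 ± 1.27, against 92.7 ± 6.02, so neither fell further with dose. Both were also called lower with Cnidii Rhizoma, Rehmanniae Radix Preparata and Astragali Radix, so they are not particular to Samul-tang. All these comparisons share the 3 vehicle libraries, so high values in the vehicle cannot be told apart from an effect of the extracts. The secretory genes REG4 and MUC2 were at -0.51 and -0.54. CXCL1 was at 2.41 ± 0.336 CPM. Called genes numbered 2966 at 500 µg/mL (1651 higher, 1315 lower), 3537 at 100 µg/mL and 1715 at 20 µg/mL, and with the library set term 191, 90 and 60. Mitochondrially encoded mRNAs held 6.705% ± 0.771, 6.373% ± 0.862 and 7.056% ± 0.453 of all counts at these doses, against 10.004% ± 1.355 in the vehicle. Without vehicle replicate 3 the counts at 500 and 100 µg/mL were 1037 and 1677, and without Samul-tang replicate 2 that at 20 µg/mL was 426.

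**Figure D3:**
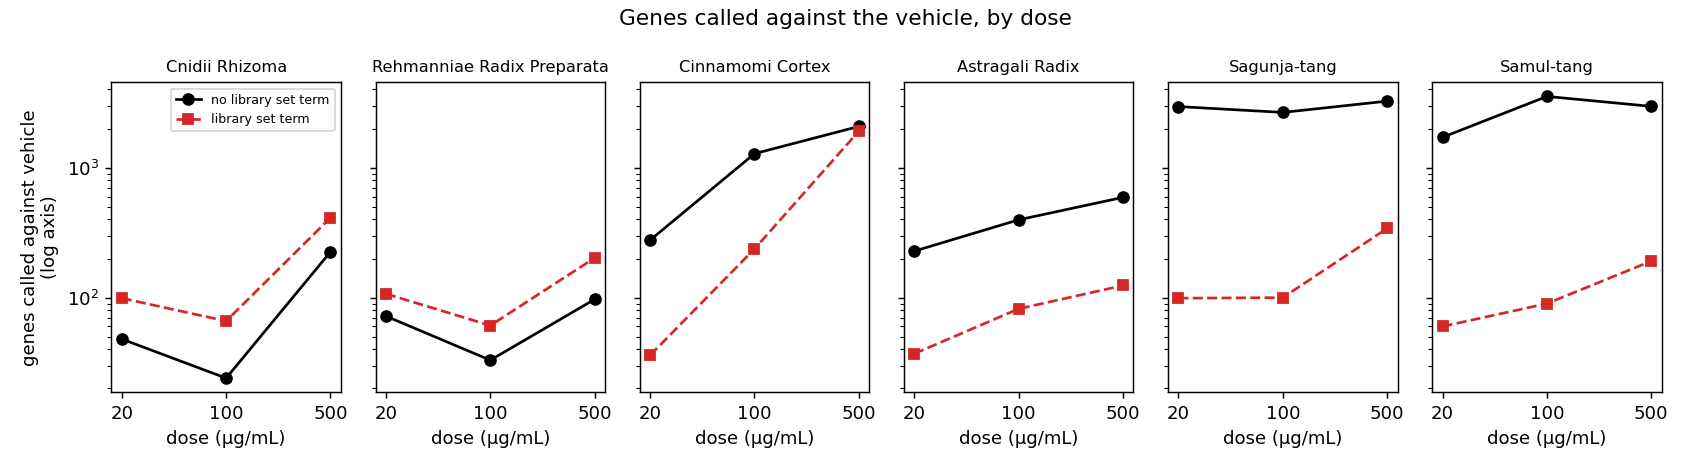
The number of genes called against the vehicle (y axis, log scale) is plotted by dose in µg/mL (x axis) for each extract, without (black) and with (red) the library set term. For Samul-tang at 100 µg/mL the counts are 3537 and 90, and for Cinnamomi Cortex at 500 µg/mL 2078 and 1910.

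CYP1A1, a target of the aryl hydrocarbon receptor, was called lower at 500 µg/mL with every extract except Rehmanniae Radix Preparata, at -2.90 (SE 0.46) with Cinnamomi Cortex, -1.82 with Cnidii Rhizoma, -1.57 with Astragali Radix, -1.51 with Sagunja-tang and -1.15 with Samul-tang. The vehicle libraries themselves were at 5.75, 0.595 and 1.1 CPM, and these calls rest mostly on the first of them. Without vehicle replicate 1 only the call with Cinnamomi Cortex was left, at -1.30 (adjusted p = 0.016), while the values with the other 4 were -0.21, 0.04, 0.09 and 0.46, none of them called.

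The second question was which changes depended on dose, from 500 against 20 µg/mL within each extract. Cinnamomi Cortex had 1651 called genes (738 higher, 913 lower), 1137 without replicate 2 at 500 µg/mL, the exception among the library sets, and 942 without replicate 3 at 20 µg/mL. The NRF2 list had 23 risen and 0 fallen of 25 (24 and 0 adjusted over the list alone) and cholesterol synthesis 22 and 0 of 25 (24 and 0 adjusted over the list alone), with adjusted p = 2.2e-08 and 0.0023 with an estimated correlation. AKR1C2 was higher by 1.61 (SE 0.09), AKR1C1 by 1.60 and CDA, cytidine deaminase, by 1.07, while MT1X was at -1.89, MT2A at -1.32 and RARRES1 at -1.28. Cnidii Rhizoma had 65 called genes (30 without replicate 1 at 500 µg/mL), with 16 of 25 NRF2 targets risen (21 adjusted over the list alone), and AKR1B10 at 0.95 and ALDH3A1 at 0.71. Its lower genes included BMF, a gene of apoptosis, at -0.60. Samul-tang had 23 (14 without replicate 1 at 500 µg/mL), with 9 of 25 NRF2 targets risen (21 adjusted over the list alone), AKR1C2 at 0.76 and ALDH3A1 at 0.60. Rehmanniae Radix Preparata had 28 (13 without replicate 2 at 20 µg/mL), with 8 of 25 risen (20 adjusted over the list alone), ALDH3A1 at 0.56 and HMOX1 at 0.45. In these 3 the NRF2 list held with an estimated correlation, at adjusted p = 3.9e-10, 5.3e-09 and 3.4e-07. Astragali Radix had 13, led by ACSS2 at -0.54 (SE 0.08) and AKR1C2 at 0.46, with SCD at -0.24, and leaving out any single library of either dose left 1 to 3. Sagunja-tang had 1, PI3 at 0.60 (SE 0.11, adjusted p = 0.016), while 1564 genes had an unadjusted p under 0.05 and DESeq2 called 45, and without replicate 2 at 20 µg/mL 57 genes were called. The PI3 call was lost without Sagunja-tang replicate 3 at 20 µg/mL (adjusted p = 0.64).

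The third question was how Samul-tang compared with other extracts at 500 µg/mL. Against Sagunja-tang, in the same library set, 52 genes were called, 5 higher and 47 lower. Of the 24 NF-kB genes 18 were lower and 0 higher (21 and 0 adjusted over the list alone; adjusted p = 6.6e-21 with an estimated correlation), with CXCL1 at -3.81 (SE 0.16, adjusted p = 3.3e-23), PI3 at -2.42, CXCL8 at -2.06 and ICAM1, an adhesion molecule, at -0.88. Of 38 interferon response genes 9 were lower and 0 higher (26 and 0 adjusted over the list alone; adjusted p = 5.1e-07 with an estimated correlation), with OAS2 at -1.42. Of 25 NRF2 targets 4 were higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 3.5e-06 with an estimated correlation), with AKR1C2 at 0.45 and AKR1B10 at 0.40.

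Against Cnidii Rhizoma, AKR1B10 was lower with Samul-tang at -0.36 (SE 0.05, adjusted p = 0.00032; -0.37 with the library set term), EPHX1 was at -0.32, CEACAM6 at -0.37 and TRIB3 at 0.46, and these last 3 calls were lost with that term (adjusted p = 0.41, 0.36 and 0.45). These were among 9 called genes, a count that does not show likeness, since 3726 genes had an unadjusted p under 0.05, 1340 an adjusted p under 0.1, DESeq2 called 966 and a fit of the 2 groups alone 2431, and without Samul-tang replicate 3 the count was 404. Against Rehmanniae Radix Preparata, NQO1 was at 0.22 (SE 0.05), CXCL8 at 0.35 and CD68 at -0.94, and 12 of 13 mitochondrially encoded mRNAs were lower (12 adjusted over the list alone; adjusted p = 0.47 with an estimated correlation). Of 2174 called genes 0 were called with the library set term, with 1538 at an unadjusted p under 0.05, and without Rehmanniae Radix Preparata replicate 2 the count was 2. Both comparisons cross the library sets.

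Paeoniae Radix, peony root, had 1 library per dose, so its values have no replicate check. In the 500 µg/mL library AKR1C2 was at 18 CPM against 10.9 ± 1.17 in the vehicle, a log2 ratio of 0.72, and PGGHG, which was called higher in 17 of the 18 tested comparisons with the vehicle, at 0.83. MUC12 was at -0.83 and MT2A at -0.77. The 33 lists were ranked by their median log2 ratio among 10000 random lists of like size and expression. To 1 decimal, 4 lists were at percentile 100. They were the NRF2 list at 0.23, the ATF4 list at 0.10, nuclear encoded OXPHOS genes at 0.09 and ribosomal proteins at 0.04. Another 3 were at percentile 0, the mitochondrially encoded mRNAs at -0.43, the metallothionein list at -0.40 and the interferon response at -0.13. These ranks ignore the correlation among list members and the spread between libraries. They therefore only order the lists and do not show that a list changed.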

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

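The comparison of Paeoniae Radix with the vehicle over the 15 panel genes was chosen only after the values were seen. Paeoniae Radix had 1 library per dose and entered none of the tested comparisons, and 2 of the 15 panel genes lay above all 3 vehicle libraries at all 3 of its doses. ASNS, asparagine synthetase, was at 53.3 CPM in the 500 µg/mL library, against 51.1 ± 1.2 CPM in the vehicle, with log2 ratios of 0.06, 0.08 and 0.15 at 500, 100 and 20 µg/mL. TRIB3, which like ASNS is induced by amino acid shortage, was at 37.5 CPM against 31.1 ± 1.55, with log2 ratios of 0.27, 0.15 and 0.29. Of the panel genes 3 lay below all vehicle libraries at all doses. With 3 values against 3, chance alone separates 10% of genes, counting both directions together. Of all 16356 genes, 2134 lay above and 2137 below, so 2 of 15 panel genes above is near the share over all genes. The doses are also not replicates of one group. No biological explanation was tested.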

How the results depend on the processing

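The tests chosen only after the results were seen are the library set term, the fit of the first library set alone and the adjusted p under 0.1. Counts are given for Cnidii Rhizoma, Rehmanniae Radix Preparata, Cinnamomi Cortex, Astragali Radix, Sagunja-tang and Samul-tang in this order. With RLE factors all 33 counts stayed within 1.5 times, as did all 10 counts from the first library set alone. Of 116 named values, 114 kept their direction and side of the threshold with RLE factors, 114 with no filter, 108 with the library set term and 96 with the 2 groups alone. With 1 library left out, 625 of 696 did so. The named values include comparisons inside a library set or balanced over the sets, where the set term changes little. For Samul-tang at 500 µg/mL against the vehicle, 160 of all 2966 called genes were also called with the set term.

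DESeq2 gave 44 and 51 genes for Cnidii Rhizoma and Rehmanniae Radix Preparata at 100 µg/mL, 424 for Cinnamomi Cortex at 20 µg/mL, 56, 45 and 40 between 500 and 20 µg/mL for Rehmanniae Radix Preparata, Sagunja-tang and Samul-tang, and 966 for Samul-tang against Cnidii Rhizoma. Its other 20 counts stayed within 1.5 times. Without a filter on low counts, Cnidii Rhizoma had 366, 182 and 185 genes at 500, 100 and 20 µg/mL, Rehmanniae Radix Preparata 265, 134 and 195, Astragali Radix 1223, 958 and 945, and Cinnamomi Cortex 949 at 20 µg/mL. Between 500 and 20 µg/mL it gave 150, 204, 72, 213 and 138 for all but Cinnamomi Cortex, 1681 for Samul-tang against Cnidii Rhizoma and 117 against Sagunja-tang, and 9 and 15 lists for Astragali Radix and Samul-tang. The cause was not tested.

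A fit of the 2 groups alone uses fewer libraries for the spread. Beside counts of 0, genes at an unadjusted p under 0.05 are given. Without any change a share of 0.05 of the 16356 genes would reach that, and the 897 below lies not far above it. It gave 10, 8 and 39 genes for Rehmanniae Radix Preparata, 701, 198 and 101 for Cinnamomi Cortex, 149, 48 and 0 for Astragali Radix, the last with 2582 at an unadjusted p under 0.05 by edgeR on all libraries and 299 by DESeq2, 27 for Cnidii Rhizoma and 2859 for Samul-tang at 20 µg/mL, 131, 6, 519, 0, 4 and 35 between 500 and 20 µg/mL, the 0 with 897 at an unadjusted p under 0.05 by edgeR on all libraries and 16 by DESeq2, and 2431 for Samul-tang against Cnidii Rhizoma.

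With the library set term the counts at 500 µg/mL were 412, 202, 124, 341 and 191 without Cinnamomi Cortex, at 100 µg/mL 66, 61, 237, 82, 100 and 90, and at 20 µg/mL 99, 36, 37, 99 and 60 without Rehmanniae Radix Preparata. Between 500 and 20 µg/mL they were 102, 59, 40 and 48 for Cnidii Rhizoma, Rehmanniae Radix Preparata, Sagunja-tang and Samul-tang, and for Samul-tang against Cnidii Rhizoma and Rehmanniae Radix Preparata 1 and 0, the latter with 1538 at an unadjusted p under 0.05 and 2571 by DESeq2 without the term. Lists numbered 9 for Astragali Radix and 17 for Samul-tang. At an adjusted p under 0.1, Samul-tang had 1340 genes against Cnidii Rhizoma and 3620 against Rehmanniae Radix Preparata. With an estimated correlation 6, 2, 2 and 3 lists were called for Cnidii Rhizoma, Astragali Radix, Sagunja-tang and Samul-tang, and with the 20 µg/mL group in place of the vehicle 16 for Astragali Radix. Of named values, DDIT3 with Cinnamomi Cortex, at 0.00 and not called, changed sign, at 0.00 with RLE factors, no filter and DESeq2, and from -0.08 to 0.11 with 1 library left out. CYP1A1 at 500 µg/mL changed sign without vehicle replicate 1, at 0.04 with Astragali Radix, 0.09 with Sagunja-tang and 0.46 with Samul-tang, and was not called there, and with 1 library left out its lowest values were -2.03, -1.98 and -1.62.

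Replicate numbers recur in every group, but no label says that they mark a shared culture or day. Deviations from group means correlated at 0.065 between libraries of the same number and -0.032 between others, 206 of 513 same-numbered pairs exceeded 0.1, and 41 of 57 libraries correlated best with their own number. Same-numbered libraries correlated at 0.176 within a sample code and 0.026 between codes, so the data hint at a shared structure inside a code. As not every same-numbered pair exceeded 0.1, the numbers were not taken to pair the libraries, and whether they do is open. With the replicate block the counts for Cnidii Rhizoma were 387, 63 and 90 at 500, 100 and 20 µg/mL, for Rehmanniae Radix Preparata 176, 71 and 114, for Astragali Radix 936, 773 and 421 and for Cinnamomi Cortex at 20 µg/mL 552. Between 500 and 20 µg/mL they were 119, 59, 20, 27 and 49 for all but Cinnamomi Cortex, and 593 for Samul-tang against Cnidii Rhizoma. The other 17 stayed within 1.5 times, and all 116 named values kept their call.

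Leaving out 1 library lowers the number behind each estimate, and 107 of 198 counts then moved by over 1.5 times. The ranges at 500 µg/mL were 81 to 159, 27 to 84, 1111 to 2090, 110 to 1201, 1306 to 3207 and 1037 to 2964, at 100 µg/mL 0 to 32, 6 to 40, 139 to 2503, 68 to 1247, 784 to 2592 and 1677 to 3290, and at 20 µg/mL 4 to 46, 14 to 90, 42 to 1223, 26 to 1656, 1150 to 2848 and 426 to 1635. Between 500 and 20 µg/mL they were 30 to 57, 13 to 32, 942 to 1809, 1 to 3, 0 to 57 and 14 to 22. For Samul-tang they were 1 to 404 against Cnidii Rhizoma, 2 to 2811 against Rehmanniae Radix Preparata and 39 to 48 against Sagunja-tang. Lists ran from 13 to 17, 14 to 17, 14 to 17, 4 to 8, 9 to 15 and 8 to 10. Depth was not varied.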

Other observations

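The tests chosen only after the result was seen are those of the library sets, GC content and extract effect for the formulae, the count by vehicle library, the size of the set difference in the 22 genes below, and the comparison of the formulae for NF-kB genes.

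Cinnamomi Cortex at 500 µg/mL also raised genes of other groups against the vehicle. Of 29 genes of the hypoxia response and glycolysis 15 rose and 1 fell (18 and 2 adjusted over the list alone), with the aldolase gene ALDOC at 0.79 (SE 0.08) and the glucose transporter gene SLC2A1 at 0.34. Of 34 immediate early genes 11 rose (14 adjusted over the list alone), with ATF3 at 0.80 and DUSP6 at 0.30, and of 36 genes of autophagy and the lysosome 14 rose and 2 fell (16 and 2 adjusted over the list alone), with NEU1 at 0.44 and SQSTM1 at 0.36. Of 19 heat shock genes 8 rose (10 adjusted over the list alone), with FKBP4 at 0.25, and of 23 chaperones of the endoplasmic reticulum 7 rose (8 adjusted over the list alone), with HSPA5 at 0.20. With an estimated correlation these 5 lists stood at adjusted p = 0.00064, 0.00072, 0.0065, 0.022 and 0.022. The tight junction genes CLDN2 and CLDN4 were at -0.59 and 0.46.

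Between 500 and 20 µg/mL, 3 of 10 targets of the aryl hydrocarbon receptor rose with Cnidii Rhizoma (4 adjusted over the list alone; adjusted p = 0.00023 with an estimated correlation) and 3 with Samul-tang (3 adjusted over the list alone; adjusted p = 7.8e-05 with an estimated correlation). CYP1A1, a member of that list, was called in neither, at -0.09 (SE 0.45) and 0.79 (SE 0.43). NRF2 targets rose in the same comparisons, and whether the receptor was active was not tested. With Astragali Radix 2 of 14 fatty acid synthesis genes fell (3 adjusted over the list alone; adjusted p = 0.0048 with an estimated correlation). Markers of other cell types did not pass the list test in any extract at 500 µg/mL against the vehicle, with adjusted p of 0.83 with Sagunja-tang for 8 fibroblast genes, 0.64 for 9 leukocyte genes and 0.47 for 6 hepatocyte genes.

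Across 16356 genes, which are not independent replicates, the change from 20 to 500 µg/mL correlated at 0.16 between Rehmanniae Radix Preparata and Cinnamomi Cortex, at 0.15 between Cnidii Rhizoma and Samul-tang and at 0.15 between the formulae, the highest of 15 pairs, and at 0.00 between Cnidii Rhizoma and Astragali Radix. Changes from the vehicle correlated at 0.34 to 0.77. Groups simulated without change against shared vehicle libraries correlated at 0.49, with a covariance of 0.0258 against 0.0297 to 0.0913 observed. The simulation held no difference between library sets, which enters the observed values. The highest covariance, 0.0913, was that of the formulae, whose libraries are all in the second set.

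For the genes called between each formula and the vehicle, a difference between library sets may be a large part of the source. The set difference was taken inside the 6 groups of Cinnamomi Cortex and Astragali Radix, across 12066 genes. The fold changes of Samul-tang and Sagunja-tang at 500 µg/mL, which use none of these libraries, correlated with it at 0.75 and 0.72. Cnidii Rhizoma and Rehmanniae Radix Preparata, whose libraries are all in the first set, gave 0.29 and 0.08. A correlation of 0.29 can therefore arise without crossing the sets. Astragali Radix and Cinnamomi Cortex gave 0.67 and 0.29, but their own libraries make up the set difference. A GC content trend was tested for Samul-tang at 500 µg/mL only. It is argued against there as the whole source, since 89.2% of the genes were still called after it was removed from each library. With the set term 6.4% as many genes were called in that comparison, which met the bound set against an effect of the extract. But the median called change kept 49.6% of its size, from 0.27 to 0.13, at an SE of 0.074 and 0.075. Since the formulae have no vehicle library in their set, their effects and the set difference cannot be told apart for most of these genes.

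A group of 22 genes, chosen after their values were seen, was called higher in at least 15 of the 18 comparisons with the vehicle. Among them KLHL17, LMF2 and SLC26A6 were called in all 18, at median log2 changes of 0.65, 0.27 and 0.45. Another 7 genes were called lower as often. In 10 simulated sets without change at most 0 such genes arose. That argues against chance values of vehicle libraries that vary independently, but not against a deviation that these libraries share. The difference between library sets is argued against as the whole source by a bound set only once the values were known, since inside the 6 groups lying in both sets it had a median of 0.14 over these genes (SD over the groups 0.06), against a median change of 0.50 outside the vehicle's set, while a stricter bound set earlier, a small share of the median change of 0.46 over all 18, was not met, so that a part stays open. Inside the vehicle's set the genes had a median change of 0.42 and were called higher in a median of 6 of the 6 comparisons, but their choice forces at least 3, so this decides nothing. Leaving out vehicle replicate 1, 2 or 3 left 6, 8 and 11 genes. That met the bound set beforehand for a single deviating vehicle library for replicates 1 and 2 but not for replicate 3. In the respective vehicle libraries 22, 21 and 21 of the genes lay below the 5th percentile of treated libraries, so all 3 were low. But the genes were chosen for low values in the vehicle, which favours this count. The count was also added afterwards, so a single deviating library stays open. With only 1 vehicle group, any feature that all vehicle libraries share, including how they were handled, stays open beside an effect common to the extracts. The lower GC slope of the vehicle libraries is one such feature.

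Of the 24 NF-kB inflammatory genes 18 were higher with Sagunja-tang at 500 µg/mL than with the vehicle (19 adjusted over the list alone), while with Samul-tang, whose libraries are in the same set, 3 were higher, among them CXCL8, and 2 lower (5 and 2 adjusted over the list alone). Against Sagunja-tang 18 were lower with Samul-tang, which argues against the difference between library sets. Of 9 leukocyte markers tested 0 were called higher with Sagunja-tang than with Samul-tang. That decides little about RNA from leukocytes, since the cells are a cultured line in which it was unlikely from the start. LYZ was at 1470 CPM in the vehicle too, and CD4 and LAPTM5 were at 0.389 and 0.667 CPM with Sagunja-tang. A single deviating library is argued against by CXCL1, at 24.1 CPM in the lowest of the 9 Sagunja-tang libraries, above 2.77 in the highest of the 9 Samul-tang libraries and 2.66 in the highest vehicle library. As a hypothesis, Sagunja-tang may act on NF-kB target genes in these cells, and whether a component such as endotoxin in the extract does so was not tested.

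The libraries of each comparison of 3 with 3 make 10 splits, too few for a share under 0.05. With fits of the 2 groups alone, the real counts at 500 µg/mL against the vehicle were 221, 10, 701, 149, 3872 and 3048 for Cnidii Rhizoma, Rehmanniae Radix Preparata, Cinnamomi Cortex, Astragali Radix, Sagunja-tang and Samul-tang, the highest other splits gave 6, 84, 2, 16, 0 and 0, and 1, 2, 1, 1, 1 and 1 splits gave as many. At 100 µg/mL the real counts were 24, 8, 198, 48, 2325 and 3257, the highest others 11, 857, 6, 54, 1 and 1, and 1, 2, 1, 2, 1 and 1 splits gave as many. At 20 µg/mL the real counts were 27, 39, 101, 0, 2809 and 2859, the highest others 27, 263, 2, 448, 1 and 0, and 2, 2, 1, 10, 1 and 1 splits gave as many. Between 500 and 20 µg/mL the real counts were 131, 6, 519, 0, 4 and 35, the highest others 4, 6, 810, 6, 3 and 7, and 1, 2, 2, 10, 1 and 1 splits gave as many. For Samul-tang against Cnidii Rhizoma, Rehmanniae Radix Preparata and Sagunja-tang the real counts were 2431, 1671 and 55, the highest others 2, 0 and 6, and 1, 1 and 1 splits gave as many. For both formulae against the vehicle, only the real split parts the library sets. The same holds for Samul-tang against Cnidii Rhizoma and Rehmanniae Radix Preparata. In these comparisons the splits cannot tell treatment from the set difference. For lists the real counts were 15, 18, 15, 6, 10 and 7, the highest others 16, 12, 14, 12, 13 and 8, and 2, 1, 1, 3, 2 and 2 splits gave as many. Thus for Cnidii Rhizoma, Astragali Radix, Sagunja-tang and Samul-tang a split mixing treated and vehicle libraries called more lists than the real one. The number of lists called at the preset correlation does not mark treatment there. The splits with 857 and 263 genes put Rehmanniae Radix Preparata replicate 1 with vehicle replicates 1 and 2, and that with 448 put Astragali Radix replicate 1 with vehicle replicates 2 and 3, and such counts point to a structure of the samples other than treatment. The split with 810 put Cinnamomi Cortex replicates 1 and 2 at 500 µg/mL with replicate 1 at 20 µg/mL, as the first principal component does, and with the library set term the real comparison gave 2259.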
